A study of Mus musculus with 28 samples.

How the data were processed

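Small RNA from mouse sperm was measured in 28 libraries, made from Trizol-extracted RNA with the Qiaseq small RNA kit. The values used were raw read counts per annotated feature, deposited by the authors in 3 tables, which held whole numbers whose totals differed between libraries. The aligner, the counting tool, the genome build and the treatment of reads with several positions were not given in the sources used here, so no positions are reported. Groups and replicate numbers were taken from the labels. The tables mark 8 feature classes, and counts were summed per feature name within a class. Genotypes in different tables were not compared directly, and doses were not tested against each other.

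miRNAs and all other features were tested as separate families in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, two-sided, with filterByExpr, TMM scaling within the family and Benjamini-Hochberg adjustment at 0.05. The 12 WT libraries were fitted together, so the groups of 2 shared the spread of the others, and the other tables were fitted with their own 8 libraries each. The Nrf2-/- and WT responses to alcohol were compared by an interaction contrast over 20 libraries. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and were tested again with an estimated correlation. fry was run for the miRNA lists. Shares of the classes and summed exon CPM of marker lists were compared by exact two-sided permutation tests, adjusted within a comparison. miRNA CPM use the TMM-scaled miRNA counts, CPM of single other features use the TMM-scaled counts of the other classes, and summed marker CPM use all counts.

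The miRNA lists were the let-7, miR-34 and miR-449, miR-10, miR-99, miR-100 and miR-125 (the miR-10 group), miR-200 with miR-205, miR-30 and miR-29 families, the miR-17-92, X-linked spermatogenesis and Dlk1-Dio3 clusters, paternal stress-responsive and Nrf2- or Keap1-targeting miRNAs, and miRNAs of liver, skeletal muscle, smooth muscle and fibroblast, red blood cell, leukocyte and brain. Other lists covered transcripts of sperm and spermatids, spermatocytes, epididymis epithelium, leukocytes, red blood cells, smooth muscle and fibroblasts and hepatocytes, Nrf2 target genes, ethanol metabolism, tRNA isoacceptors, and the L1Md, IAP, RLTR, B1 and B2 repeats in sense and antisense. The lists, comparisons, tests and alternative settings were fixed before the data were examined, except for those named next. Summed marker values and their exact tests, the tests without miRNAs that have gaps, the epididymis covariate and the omission of WT controls 1 and 3 together were added after the data were seen. The list tests with each library left out were not planned either, nor was the estimated correlation for lists other than miRNA lists.

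By rule, features were named as follows. For miRNAs past the threshold with a mean of at least 10 CPM, up to 10 rises and up to 10 falls were named. Where fewer than 10 passed, the 10 with the lowest unadjusted p were given as values. The 10 most abundant miRNAs per table, 2 to 4 members with the lowest adjusted p per list described, up to 5 rises and 5 falls among other features past the threshold with a mean of at least 10 CPM, and Nfe2l2 were also named.

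A gap was defined as a count of 0 where at least 50 reads were expected from the other libraries, with at least 3 libraries above 0 and a lowest nonzero count of at least 10. Depth ran from 1993933 to 11119711 counts per library. Shares in single libraries carry 95% Wilson intervals, and intervals and floors of 3 counts cover counting error only. Relations between libraries used deviations from group means, with 100000 permutations. The pipeline was tested on simulated data with known changes in counts resembling the low-dose, Nrf2-/- and liver KO comparisons. The other comparisons were not simulated. For miRNAs changed 4-fold the pipeline recovered 33.3% in the low-dose design, 2.63% in the Nrf2-/- design and 95.7% in the liver KO design. In that order, 169 of 338, 118 of 237 and 147 of 295 miRNAs were changed at some fold. With so many changes the adjusted threshold is easier to pass, so these percentages may be too high for data with few changed miRNAs. Among other features, false calls were 13 of 139 in the low-dose design, 3 of 67 in the Nrf2-/- design and 3 of 134 in the liver KO design.

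Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, the total of all classes as library size, no filter, only the groups compared, a replicate block, each library left out in turn and a threshold of 0.1. For class shares the most abundant class was left out of the denominator. For the interaction, WT high dose alone replaced the mean of the doses. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for shares, permutation tests and figures.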

Results

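Small RNA was sequenced from mouse sperm in 28 libraries, each from total RNA extracted with Trizol and prepared with the Qiaseq small RNA kit. The wild type (WT) set held 4 control libraries with no alcohol exposure, 4 at a low dose of alcohol, 2 at a medium dose and 2 at a high dose, and the amounts behind these names were not given in the sources used here. A second set came from Nrf2-/- mice, with 4 control and 4 ethanol libraries. The last set held 4 libraries from mice with a floxed Nrf2 gene (Nrf2 flox) and 4 from mice lacking Nrf2 in the liver (Nrf2 liver KO). Nrf2, the product of the gene Nfe2l2, is a transcription factor that switches on antioxidant and detoxification genes. Each set had a deposited table of read counts, and the genome build was not given, so features are identified by name and not by position. Total counts ran from 1993933 (WT control 3) to 11119711 (WT control 1) in the WT set, from 3922109 to 6448390 in the Nrf2-/- set, and from 2567463 to 4394714 in the Nrf2 flox and liver KO set.

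Reads fell on miRNAs, piRNA clusters, structural RNAs (mostly tRNA), exons, introns, transposable elements in sense and antisense, and miRNA hairpins. In WT controls, piRNA clusters held 28.9% ± 12.8 (SD, n = 4) of the counts and miRNAs held 11.3% ± 5.07 (SD, n = 4). In Nrf2-/- controls, miRNAs held 32.9% ± 12.6 (SD, n = 4), and in Nrf2 flox libraries they held 17.99% ± 3.58 (SD, n = 4). WT control 1 stood apart from the other WT controls: structural RNA made up 75.8% of its counts (95% Wilson interval 75.7% to 75.8%), against 22.5% to 28.7% in the others. Its tRNA-Gly-GGY reads alone made up 27.3% of its counts (95% Wilson interval 27.2% to 27.3%), against 4.32% in WT control 2. These intervals cover counting error only.

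**Figure D1:**
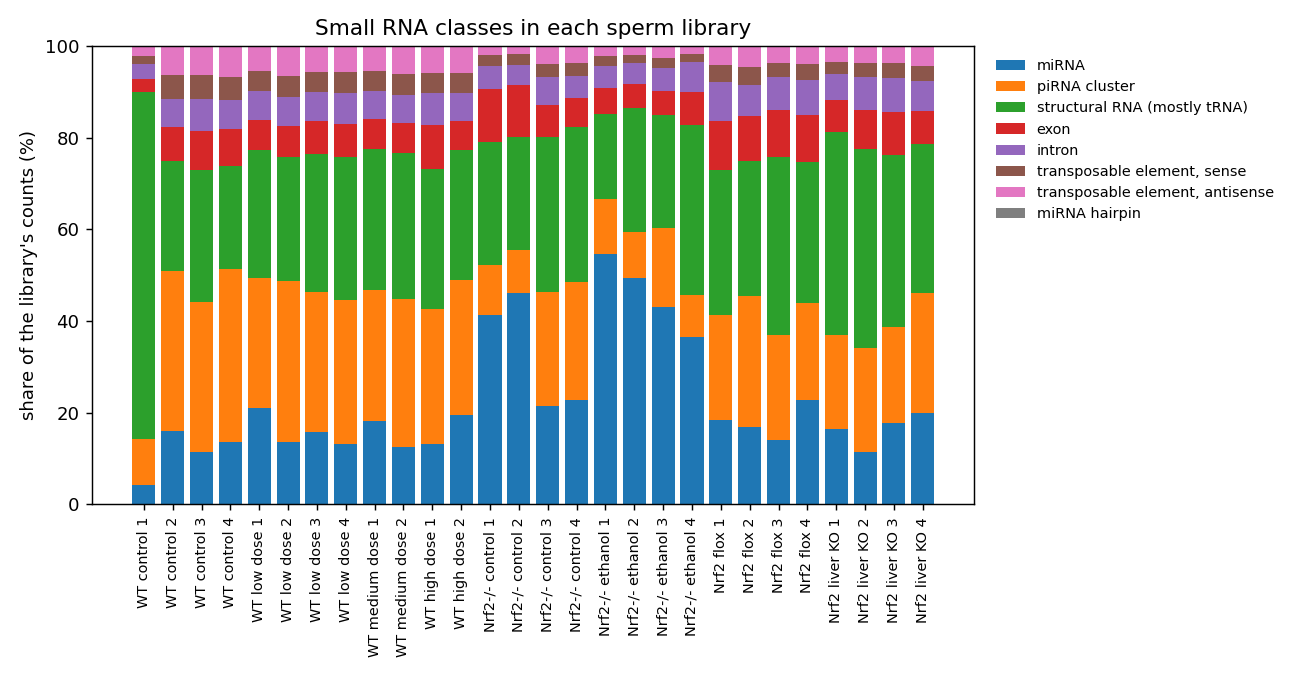
Stacked bars give the share of each library's counts (percent, y axis) in each small RNA class for the 28 sperm libraries (x axis). WT control 1 is the bar with 75.8% structural RNA, and the other WT controls lie between 22.5% and 28.7%.

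The most abundant miRNAs were miR-16-5p, let-7 members and miR-191-5p. miR-16-5p made up 31.2% of the miRNA counts in the WT table, 20.4% in the Nrf2-/- table and 26.4% in the Nrf2 flox and liver KO table. let-7c-5p, a member of a family that restrains growth and marks differentiated cells, made up 25.2% over the 8 Nrf2-/- libraries, with a control mean of 164540 CPM and an ethanol mean of 334720 CPM, while miR-16-5p was at 225040 CPM in the same controls. let-7a-5p made up 7.44%, 14.6% and 4.48% in the WT, Nrf2-/- and Nrf2 flox and liver KO tables, and miR-191-5p made up 5.11%, 6.09% and 14.1%. miR-34c-5p, abundant in male germ cells, made up 4.20% of miRNA counts in the WT table. The remaining miRNAs of the 10 most abundant were let-7c-5p, miR-669a-3p, let-7f-5p, miR-125b-5p, miR-19b-3p and miR-30c-5p in WT, let-7b-5p, let-7d-5p, let-7f-5p, let-7g-5p, miR-10a-5p and miR-143-3p in Nrf2-/-, and let-7b-5p, let-7c-5p, let-7f-5p, miR-125b-5p, miR-143-3p, miR-25-3p and miR-93-5p in the Nrf2 flox and liver KO table.

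Some abundant miRNAs were listed at 0 in single libraries. miR-16-5p was listed at 0 in WT control 4 and at 62919 to 575837 counts in the other WT libraries, and let-7c-5p was listed at 0 in WT control 3 and at 12202 to 68216 counts elsewhere. In all, 52 WT miRNAs had such gaps in 144 entries and 38 Nrf2-/- miRNAs in 64 entries, while the Nrf2 flox and liver KO table had 0. miR-465a-3p, miR-465b-3p and miR-465c-3p, near-identical copies of a testis miRNA, were listed at 0 in the same 8 WT libraries. Whether reads could be assigned to a single copy was not tested.

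The low-dose comparison asks which sperm RNAs differ after low alcohol exposure. Summed marker exons of red blood cells were higher in all 4 low-dose libraries than in every WT control. Exon counts of the hemoglobin genes and the other red blood cell markers summed to 50.1 CPM (counts scaled to library size) ± 15.1 (SD, n = 4) at low dose and 5.76 CPM ± 5.23 (SD, n = 4) in controls, an 8.69-fold difference. miR-451a, which is processed in developing red blood cells, was at 2217 CPM ± 762 (SD, n = 4) against 243 CPM ± 118 (SD, n = 4). The miR-10, miR-99, miR-100 and miR-125 family (the miR-10 group), some of which lie in Hox gene clusters, was lower as a list in the test with a preset correlation, but 0 members passed and the list had adjusted p = 0.635 with an estimated correlation. Of its members, miR-10b-5p was at 2659 CPM ± 502 (SD, n = 4) against 9899 CPM ± 9322 (SD, n = 4).

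As a list, red blood cell miRNAs rose at low dose, with 6 of 7 tested members higher and a median log2 change of 2.79 (camera adjusted p = 0.000468). It had adjusted p = 0.211 with an estimated correlation. miR-451a was higher by 3.19 (SE 0.79) and miR-144-5p by 2.79 (SE 0.89) on the log2 scale. miR-486a-5p and miR-486b-5p, copies that reads may not separate, were at 1144 CPM ± 436 (SD, n = 4) and 1155 CPM ± 426 (SD, n = 4) at low dose. Both were listed at 0 in WT control 1, where 268 and 254 reads were expected, and this gap lowers their control means. In the list, 0 members passed over all miRNAs and 4 passed when adjusted over the list alone. Without miRNAs that have gaps, the list kept 4 members and an adjusted p of 0.0254.

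As a list, exon counts of red blood cell genes also rose, with 4 of 4 tested genes higher and a median log2 change of 3.02 (camera adjusted p = 5.17e-10). The list had adjusted p = 0.113 with an estimated correlation. Hbb-bs, a beta globin gene, was at 19.0 CPM ± 5.06 (SD, n = 4) against 2.09 CPM ± 1.99 (SD, n = 4), and Hbb-bt was higher by 2.86 (SE 0.68) on the log2 scale. Hba-a1 and Hba-a2, alpha globin copies that reads may not separate, were higher by 3.06 and 2.99. Of these genes, 0 passed over all features and 4 passed when adjusted over the list alone. The exact two-sided permutation test of the summed exon CPM gave p = 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p of 0.257 over the 9 marker lists, the lowest that 1 list alone can reach.

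**Figure D2:**
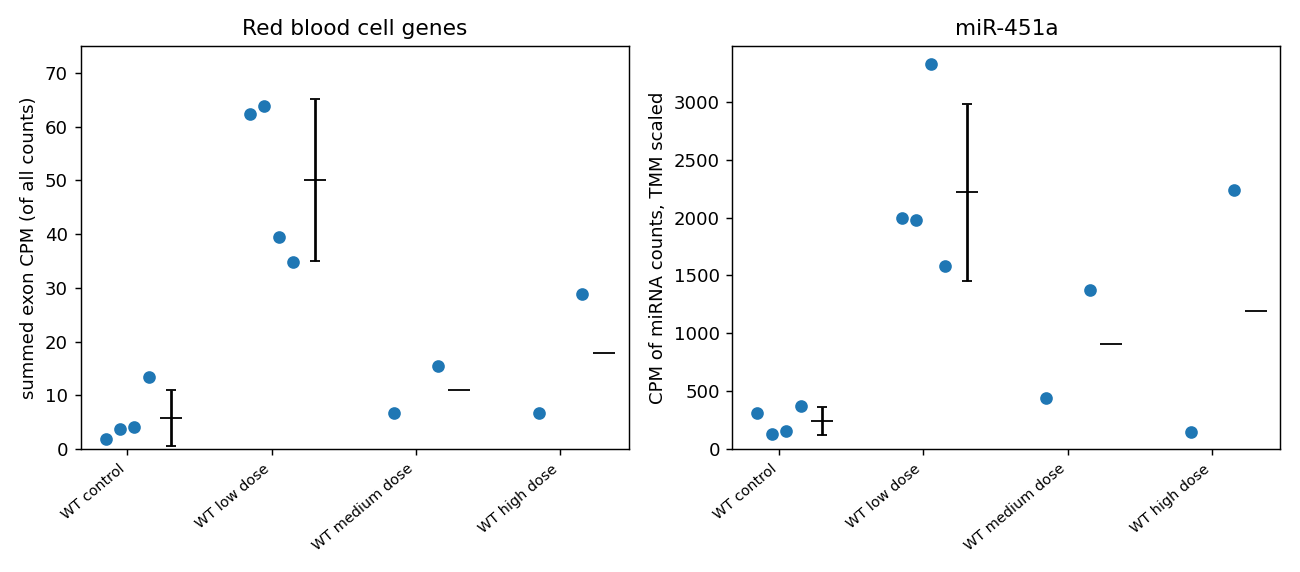
Points are WT libraries by dose group (x axis): on the left the summed exon CPM of red blood cell genes (of all counts) and on the right miR-451a CPM (of miRNA counts, TMM scaled), with the group mean as a tick and the SD as bars where a group has more than 2 libraries. The 4 low-dose libraries lie between 34.7 and 63.8 summed exon CPM, above the highest control at 13.5.

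The miR-10 group fell in the list test, with 10 of 10 members lower and a median of -1.35 (adjusted p = 0.00152), and it had adjusted p = 0.635 with an estimated correlation. miR-99a-5p was at 346 CPM ± 151 (SD, n = 4) against 1028 CPM ± 739 (SD, n = 4), and miR-10a-5p was lower by a log2 value of -1.77 (SE 0.75). The miR-29 family, known to target collagen and DNA methyltransferase transcripts, fell with 5 of 5 members lower and a median of -1.24 (adjusted p = 0.0169; adjusted p = 0.635 with an estimated correlation). miR-29c-3p was at 246 CPM ± 67.8 (SD, n = 4) against 940 CPM ± 588 (SD, n = 4), and miR-29b-3p had a log2 value of -1.24 (SE 0.46). The miR-17-92 and paralogue clusters, growth-promoting miRNAs, rose with 9 of 13 members higher and a median of 0.35 (adjusted p = 0.0258; adjusted p = 0.635 with an estimated correlation). miR-25-3p was higher by 1.07 (SE 0.33), miR-106b-3p by 1.54 (SE 0.53) and miR-92a-3p by 1.11 (SE 0.48). In each of these 3 lists, 0 members passed over all miRNAs and 0 passed when adjusted over the list alone. Without WT control 1, the adjusted p became 0.0518 for miR-10 group, 0.158 for miR-29 and 0.508 for miR-17-92. With the epididymis covariate the miR-17-92 call ended at 0.0517. Without WT low dose 4, it became 0.0655 for miR-29 and for miR-17-92, and without WT control 2 it became 0.0664 for miR-29.

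The remaining tested miRNA lists did not pass at low dose. Their adjusted p values were 0.0625 for smooth muscle and fibroblast, 0.182 for the miR-200 family with miR-205, 0.380 for the miR-34 and miR-449 family, the X-linked spermatogenesis cluster and the liver list, 0.542 for the Dlk1-Dio3 cluster, 0.642 for leukocyte, 0.739 for the paternal stress-responsive, skeletal muscle and brain lists, and 0.909 for the let-7 family, the miR-30 family and the Nrf2- or Keap1-targeting miRNAs. The median, mean and test differed in sign for the miR-34 and miR-449, miR-200 with miR-205, miR-30, Nrf2- or Keap1-targeting and brain lists.

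At the level of single miRNAs, edgeR called 0 of 338 at low dose, and 45 had an unadjusted p under 0.05 (18 higher and 27 lower) where chance gives 16.9. DESeq2 called 24, of which 15 were higher and 9 lower. The 10 miRNAs with the lowest p, given as values, included miR-101a-3p at 147 CPM ± 53.8 (SD, n = 4) against 873 CPM ± 280 (SD, n = 4), the precursor-named entry mir-451a at 3805 CPM ± 527 (SD, n = 4) against 366 CPM ± 160 (SD, n = 4), and the epithelial miR-205-5p with a log2 value of -2.99. WT control 1, at 7408 CPM, carried most of the miR-205-5p control mean of 2413 CPM ± 3333 (SD, n = 4), and without it the log2 value was -1.23. miR-190a-5p had -1.35 and mir-5121 had -4.20, the latter with 314 CPM in WT control 1 against a control mean of 98.4 CPM ± 144 (SD, n = 4) and a log2 value of -2.23 without that library. The others were miR-451a, miR-144-5p, miR-25-3p, miR-486a-5p and miR-486b-5p. By DESeq2, miR-101a-3p, mir-451a and miR-451a were among those called, all with the same direction.

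Among the other RNAs, edgeR called 10 of 17937 features at low dose. All were introns and higher in 4 of 4 low-dose libraries than in every control. An unadjusted p under 0.05 was found for 1244 features, where chance gives 896.8. Abcg2, which encodes an efflux transporter, was at 39.4 CPM ± 11.9 (SD, n = 4) against 10.4 CPM ± 4.95 (SD, n = 4), a log2 rise of 1.97 (adjusted p = 0.00670). Plcb1, a phospholipase of calcium signalling, rose by 1.20 (adjusted p = 0.0226), and Tanc2, a scaffold protein, rose by 1.13 (adjusted p = 0.0454). The other 7, Kcnj16, Ptgs2os, Pcmtd1, Pls3, 4932438A13Rik, Myo6 and Kmt2c, averaged under 10 CPM over the WT libraries and were named after their values were seen. The count became 102 with no filter and 139 with the summed epididymis exons as a covariate. It became 1 without WT control 1, 0 without WT control 2, WT control 4 or WT low dose 1, 5 without WT low dose 2 or 3, 3 without WT low dose 4 and 21 without WT control 3.

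Exons of Nrf2 target genes fell as a list at low dose, with 18 of 19 genes lower and a median of -0.73 (camera adjusted p = 2.34e-07, and 0.670 with an estimated correlation). Their summed exon CPM was 50.4 ± 16.7 (SD, n = 4) against 77.3 ± 37.5 (SD, n = 4), with an exact permutation p of 0.257 (adjusted p = 0.463). Over the 28 libraries, as deviations from group means, these exons followed those of epididymis epithelium (r = 0.973, permutation p = 1e-05). Gsta3, a glutathione transferase, had a log2 value of -1.93 and G6pdx, the NADPH-producing glucose-6-phosphate dehydrogenase, -1.47, and 0 genes passed over all features and 1 adjusted over the list alone. Leukocyte exons rose in 5 of 5 genes, by a median of 0.85 (adjusted p = 0.00212; adjusted p = 0.156 with an estimated correlation), among them Lyz2 at 1.38 and Ptprc at 1.63, with 0 passing over all features and 2 adjusted over the list alone. Epididymis epithelium exons fell in 7 of 9 genes, by a median of -0.80 (adjusted p = 0.0221; adjusted p = 0.924 with an estimated correlation), with Cd52, a sperm-coating protein of the epididymis, at -1.25 and Clu at -1.24. In that list 0 genes passed over all features and 0 adjusted over the list alone. The leukocyte call ended without WT low dose 1 (adjusted p = 0.0560) or WT low dose 3 (0.133), and the epididymis call ended without any of WT control 1, 3 and 4 and WT low dose 2 and 4 (0.0564 to 0.226).

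tRNA reads fell as a list at low dose, with 10 of 11 isoacceptors lower and a median of -1.15 (adjusted p = 0.0281; adjusted p = 0.924 with an estimated correlation). Without WT control 1, the library with 75.8% structural RNA, the direction of this list turned to higher (adjusted p = 0.195). tRNA-Glu-GAA had a log2 value of -1.04 and tRNA-Asp-GAY -0.61, and 0 isoacceptors passed over all features and 1 adjusted over the list alone. The tRNA call also ended without WT low dose 1 (0.0502), WT low dose 2 (0.1002) or WT low dose 4 (0.0566). Lists that did not pass were sperm and spermatid transcripts (adjusted p = 0.267), spermatocyte transcripts (0.517), smooth muscle and fibroblast (0.599, where the median was -0.22 and the test pointed up), hepatocyte (0.788) and ethanol metabolism (0.0636). Families of transposable elements had adjusted p values from 0.267 (IAP antisense) to 0.866 (RLTR antisense), with L1Md, B1 and B2 between them. IAP sense and RLTR antisense had a median, mean and test that differed in sign.

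Class shares were compared by exact tests, in which 1 class alone cannot pass over 8 classes with 4 against 4 libraries, since its adjusted p cannot fall below 0.229. At low dose miRNAs held 15.9% ± 3.65 (SD, n = 4) at low dose against 11.3% ± 5.07 (SD, n = 4), and piRNA clusters held 31.4% ± 2.89 (SD, n = 4) against 28.9% ± 12.8 (SD, n = 4). Without WT control 1, the difference in the share of counts moved from 4.58 to 2.23 percentage points for the class miRNA and turned from 2.52 to -3.79 for piRNA clusters. The lowest exact permutation p was 0.0286, for miRNA hairpins at 0.121% ± 0.0210 (SD, n = 4) against 0.0760% ± 0.0366 (SD, n = 4), higher in all 4 low-dose libraries than in every control (0.102% to 0.139% against 0.0227% to 0.1004%), which gave that adjusted p of 0.229. WT control 1, at 0.0227%, lowered the control mean, and the other WT controls held 0.0814% to 0.1004%.

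The medium-dose and high-dose groups had 2 libraries each and ask the same question at higher exposure. The count column of WT medium dose 1 has a name that begins with the letter of the high-dose columns, and the labels were followed, so the medium-dose and high-dose results rest on that label while the pooled comparison does not. Red blood cell miRNAs and exons were higher than in controls in the list tests with a preset correlation, with 0 members past the threshold over all features. With an estimated correlation the miRNA list had adjusted p = 0.625 at medium and 0.775 at high dose, and the exon list 0.743 and 0.791. miR-451a was at 904 CPM ± 660 (SD, n = 2) at medium and 1193 CPM ± 1478 (SD, n = 2) at high dose against 243 CPM ± 118 (SD, n = 4), and at high dose its log2 value turned from 2.30 to -0.77 without WT high dose 2. The summed red blood cell exon CPM was 11.1 ± 6.26 (SD, n = 2) at medium and 17.8 ± 15.7 (SD, n = 2) at high dose, with 1 library of each dose inside the control range. In an exact test, 4 against 2 libraries cannot reach a p below 0.0667. The doses were not tested against each other.

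At medium dose, 2 of the miRNA lists passed. The miR-10 group fell with 10 of 10 members lower and a median of -1.27 (adjusted p = 0.00619; adjusted p = 0.625 with an estimated correlation), with miR-10a-5p at -2.18 and miR-99a-5p at -1.48. Red blood cell miRNAs rose with 6 of 7 members higher and a median of 1.38 (adjusted p = 0.0314; adjusted p = 0.625 with an estimated correlation). In both lists 0 members passed over all miRNAs and 0 adjusted over the list alone. edgeR called 0 miRNAs, with 11 at an unadjusted p under 0.05, fewer than the 16.9 that chance gives. DESeq2 called 7, which became 0 without miRNAs that have gaps. Among the 10 with the lowest p, mir-451a was at 1887 CPM ± 1673 (SD, n = 2), miR-205-5p had a log2 value of -3.26 (-1.58 without WT control 1), miR-101a-3p -1.85, the muscle miRNA miR-1a-3p -2.59 (-1.47 without WT control 1), miR-184-3p 0.96 and miR-191-5p 0.97. miR-328-3p, miR-142a-5p and miR-671-5p were listed at 0 in both medium-dose libraries, and miR-200c-3p was listed at 0 in all WT controls. The red blood cell call ended without miRNAs that have gaps (0.243), without WT medium dose 1 (0.0528) or WT medium dose 2 (0.691), and the miR-10 group call without WT control 1 (0.0567) or WT medium dose 2 (0.691).

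Exon lists at medium dose showed sperm and spermatid transcripts higher, with 18 of 20 genes and a median of 0.34 (camera adjusted p = 0.000770, and 0.743 with an estimated correlation). Their summed exon CPM was 861 ± 47.9 (SD, n = 2) against 621 ± 187 (SD, n = 4), with an exact permutation p of 0.267 (adjusted p = 0.72). WT control 1 was at 342 CPM and the other WT controls at 681 to 736 CPM. These CPM are scaled to all counts, of which structural RNA made up 75.8% in WT control 1, so its low value depends on that scaling. Smcp, a protein of the sperm mitochondrial capsule, was higher by 0.64 and the transition protein gene Tnp1 by 0.87. Nrf2 target genes fell in 18 of 19 genes, by a median of -0.87 (camera adjusted p = 1.51e-06), with Gclm, which makes glutathione, at -1.74 and Gstm1 at -2.02. Their summed exon CPM was 41.5 ± 22.3 (SD, n = 2) against 77.3 ± 37.5 (SD, n = 4), with an exact permutation p of 0.267 (adjusted p = 0.72). Epididymis epithelium genes fell in 8 of 9 (median -0.60, adjusted p = 0.0245), red blood cell genes rose in 4 of 4 (median 0.94, adjusted p = 0.0275), and RLTR retroviral repeats rose in sense (96 of 148, median 0.13) and antisense (93 of 140, median 0.16), each with an adjusted p of 0.0275. All 5 of these lists had adjusted p = 0.743 with an estimated correlation, and in each list 0 members passed over all features and 0 adjusted over the list alone. Without WT medium dose 2, all 6 list calls at medium dose ended (adjusted p 0.187 to 0.988) and both RLTR directions turned. Single WT controls also ended calls: the epididymis call ended without WT control 1 (0.0521), the red blood cell exon call without WT control 1 (0.0646) or 2 (0.0657), the RLTR sense call without WT control 3 (0.153) or 4 (0.0605), and the RLTR antisense call without WT control 2 (0.0620) or 4 (0.0657). With the epididymis covariate, the sperm (0.128), red blood cell exon (0.138), red blood cell miRNA (0.121), RLTR sense (0.747) and RLTR antisense (0.655) calls ended. In the let-7, miR-200 with miR-205, X-linked spermatogenesis, liver and leukocyte miRNA lists and in IAP sense, the median, mean and test differed in sign. edgeR called 0 other features, and 9 with no filter. An unadjusted p under 0.05 was found for 772, fewer than the 896.8 that chance gives. Without WT medium dose 1, edgeR called 2 miRNAs and 2 other features.

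At high dose, the red blood cell miRNAs rose with 6 of 7 members higher and a median of 1.69 (adjusted p = 0.0423; adjusted p = 0.775 with an estimated correlation), with 0 members past the threshold over all miRNAs and 0 adjusted over the list alone. edgeR called 0 miRNAs, with 9 at an unadjusted p under 0.05, fewer than the 16.9 that chance gives. DESeq2 called 7, which became 0 without miRNAs that have gaps. Among the 10 with the lowest p, mir-451a had a log2 value of 3.06, miR-451a 2.30, miR-486a-5p 3.11, miR-1981-5p 2.25, let-7c-2-3p 1.69, miR-106b-3p 1.34 and miR-30c-2-3p -1.41. The miR-486a-5p value includes its gap in WT control 1. miR-743a-5p, miR-141-3p and mir-466b-1 were listed at 0 in both high-dose libraries. The list call ended without miRNAs that have gaps (0.465), without WT control 1 (0.0518) or WT high dose 2 (0.797), and miR-451a itself turned to -0.77 without WT high dose 2. edgeR called 0 other features, with 489 at an unadjusted p under 0.05, fewer than the 896.8 that chance gives. The count of miRNAs became 5 without WT high dose 1 and 3 without WT high dose 2.

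The exon lists at high dose again included red blood cell genes, higher in 4 of 4 by a median of 1.31 (adjusted p = 0.00457; adjusted p = 0.791 with an estimated correlation), such as Hbb-bs at 1.52 and Hbb-bt at 1.39. tRNA isoacceptors fell in 10 of 11, by a median of -1.44 (adjusted p = 0.00457; adjusted p = 0.791 with an estimated correlation), and without WT control 1 the direction turned (0.857). Antisense reads of B1 repeats fell in 10 of 10 names, by a median of -0.22 (adjusted p = 0.0421; adjusted p = 0.791 with an estimated correlation). In these 3 lists 0 members passed over all features and 0 adjusted over the list alone. Without WT high dose 2 the red blood cell call ended (0.942), without WT high dose 1 the tRNA call (0.121) and the B1 call (0.984) ended, and the B1 call also ended without WT control 1, 2 or 4 (0.121 to 0.144). With the epididymis covariate the tRNA (0.173) and B1 antisense (0.565) calls ended. Median, mean and test differed in sign for the let-7, miR-30, Nrf2- or Keap1-targeting, skeletal muscle, smooth muscle and fibroblast, leukocyte and brain miRNA lists. Epididymis epithelium genes were at 1927 summed CPM in WT high dose 1 and 297 in WT high dose 2.

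Medium and high dose were also pooled into 4 libraries. The red blood cell miRNAs rose with a median of 1.54 in 6 of 7 members (adjusted p = 0.0154; adjusted p = 0.601 with an estimated correlation), and the red blood cell exons rose with a median of 1.13 in 4 of 4 genes (adjusted p = 0.00289; adjusted p = 0.849 with an estimated correlation). Nrf2 target genes fell in 13 of 19 by a median of -0.23 (adjusted p = 0.0131) and tRNA isoacceptors in 10 of 11 by a median of -1.20 (adjusted p = 0.0117), both with adjusted p = 0.849 with an estimated correlation. The summed exon CPM of the Nrf2 targets pointed the other way, at 89.2 ± 93.5 (SD, n = 4) against 77.3 ± 37.5 (SD, n = 4), with an exact permutation p of 0.886 and a high-dose mean of 137. The high-dose libraries were at 45.7 and 228 CPM and the medium-dose libraries at 25.8 and 57.3 CPM. The higher pooled mean thus rested on 1 library. Over these 4 lists 0 members passed over all features, and adjusted over the list alone 1 tRNA isoacceptor and 0 members of the others passed. Sperm and spermatid exons summed to 855 CPM ± 59.9 (SD, n = 4) against 621 CPM ± 187 (SD, n = 4), higher in 4 of 4 pooled libraries than in every control (exact permutation p = 0.0286, adjusted p = 0.257). WT control 1, at 342 CPM, lowered the control mean, and the other WT controls were at 681 to 736 CPM. These CPM are scaled to all counts, of which structural RNA made up 75.8% in WT control 1 and 22.5% to 28.7% in the others. The low value of WT control 1 and the separation from every control thus depend on that scaling.

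edgeR called 0 miRNAs for the pooled doses (21 at an unadjusted p under 0.05 where chance gives 16.9, smallest adjusted p 0.748). DESeq2 called 13, of which 1, mir-451a, was called without miRNAs that have gaps. mir-451a had a log2 value of 2.71, miR-451a 2.10, miR-486a-5p 2.92, miR-101a-3p -1.67 and miR-205-5p -2.37, which became -0.68 without WT control 1. The miR-486a-5p value includes its gap in that control. The others of the 10 with the lowest p were miR-141-3p, miR-328-3p and miR-743a-5p, each listed at 0 in at least 1 pooled library, and miR-465b-3p and miR-465c-3p, listed at 0 in all 4. Of the other features 0 passed in edgeR, while 4 passed with no filter and 1 with the epididymis covariate. An unadjusted p under 0.05 was found for 501, fewer than the 896.8 that chance gives. Without WT high dose 1, 5 miRNAs and 5 other features were called, without WT medium dose 1, 2 miRNAs and 3 other features, and without WT high dose 2, 3 miRNAs. The red blood cell miRNA call ended without miRNAs that have gaps (0.236), without WT high dose 2 (0.0994) or WT medium dose 2 (0.257). The Nrf2 target direction turned without WT high dose 2 (0.814), and its call also ended without WT control 1 (0.0576), WT control 3 (0.126), WT control 4 (0.152) or WT medium dose 2 (0.389). The tRNA direction turned without WT control 1 (0.355), and its call ended without WT high dose 1 (0.0505) or WT medium dose 2 (0.0609). The red blood cell exon call ended without WT control 1 (0.0576), WT medium dose 2 (0.0575) or WT high dose 2 (0.101). Median, mean and test differed in sign for the let-7, X-linked spermatogenesis, Dlk1-Dio3, Nrf2- or Keap1-targeting, smooth muscle and fibroblast, leukocyte and brain miRNA lists, and for the epididymis, ethanol metabolism, L1Md sense and IAP antisense lists.

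Pooling all 8 alcohol libraries asks which sperm RNAs differ with any exposure. As lists, in the test with a preset correlation, red blood cell miRNAs were higher and the miR-29 family and the miR-10 group were lower than in the 4 controls, with 0 members past the threshold over all miRNAs. These lists had adjusted p = 0.314, 0.696 and 0.696 with an estimated correlation. miR-101a-3p, a miRNA known to target the histone methyltransferase Ezh2, was at 212 CPM ± 135 (SD, n = 8) against 873 CPM ± 280 (SD, n = 4). miR-191-5p was at 59228 CPM ± 12401 (SD, n = 8) against 31198 CPM ± 11604 (SD, n = 4). Neither passed the test over all miRNAs.

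Red blood cell miRNAs rose by a median of 1.95 in 6 of 7 members (adjusted p = 0.00194; adjusted p = 0.314 with an estimated correlation; 0 passed over all miRNAs and 2 adjusted over the list alone). The miR-10 group fell in 10 of 10 (median -0.84, adjusted p = 0.00923), the miR-29 family fell in 5 of 5 (median -0.92, adjusted p = 0.0257) and the miR-17-92 clusters rose in 8 of 13 (median 0.25, adjusted p = 0.0257). These 3 lists had adjusted p = 0.696 with an estimated correlation, and in them 0 members passed over all miRNAs and 0 adjusted over the list alone. Without WT control 1 all 3 calls ended, with adjusted p values of 0.221, 0.221 and 0.657 in that order, and the miR-10 group call also ended without WT medium dose 2 (0.0550) or WT high dose 2 (0.0595). The red blood cell call ended without miRNAs that have gaps (0.0692). The miR-200 family with miR-205 did not pass (adjusted p = 0.136), while 4 of its members passed when adjusted over the list alone. Signs of median, mean and test differed for the let-7, miR-34 and miR-449, X-linked spermatogenesis, Nrf2- or Keap1-targeting, leukocyte and brain lists.

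edgeR called 0 miRNAs with any alcohol (40 at an unadjusted p under 0.05 where chance gives 16.9, smallest adjusted p 0.360). DESeq2 called 20, of which 12 were higher and 8 lower. The 10 with the lowest p also held mir-451a (log2 2.93), miR-451a (2.46), miR-486a-5p (3.35), miR-184-3p (0.91), miR-205-5p (-2.57), miR-1a-3p (-1.87), mir-5121 (-2.92) and miR-29c-3p (-1.42). The miR-486a-5p value includes its gap in WT control 1. Without WT control 1, miR-205-5p had -0.87, miR-1a-3p -0.71 and mir-5121 -0.99. Among the other RNAs, 1 feature passed, with 725 at an unadjusted p under 0.05, fewer than the 896.8 that chance gives. The feature was Vaultrc5, a vault RNA that is part of vault ribonucleoprotein particles. It was at 48.2 CPM ± 10.5 (SD, n = 8) against 113 CPM ± 27.2 (SD, n = 4), a log2 change of -1.26 (adjusted p = 0.0130). It was lower in 8 of 8 alcohol libraries than in every control. The call ended without WT control 1 (0.142), WT control 3 (0.155), WT low dose 4 (0.0530) or WT medium dose 2 (0.172), and the count of other features became 5 without WT high dose 1, 2 without WT medium dose 1, 14 with no filter and 4 with the epididymis covariate. The count of miRNAs became 5 without WT high dose 1, 2 without WT high dose 2 and 3 without WT medium dose 1. No small RNA class passed for any alcohol (miRNAs 15.9% ± 3.30, SD, n = 8, exact permutation adjusted p = 0.372), and 4 classes passed without WT control 1. Sense reads of transposable elements held 4.30% to 4.73% in the alcohol libraries and 4.96% to 5.14% in the WT controls other than WT control 1. Structural RNA lay the other way, at 27.1% to 31.8% against 22.5% to 28.7%.

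Red blood cell exons rose with any alcohol in 4 of 4 genes, by a median of 1.76 (adjusted p = 8.53e-07; adjusted p = 0.304 with an estimated correlation; 0 passed over all features and 4 adjusted over the list alone). Nrf2 target genes fell in 16 of 19 (median -0.38, adjusted p = 7.70e-05; adjusted p = 0.888 with an estimated correlation), with Gclm at -0.88 and Srxn1, a sulfiredoxin, at -0.70. Their summed exon CPM was 69.8 ± 65.6 (SD, n = 8) against 77.3 ± 37.5 (SD, n = 4), with an exact permutation p of 0.901. Epididymis epithelium exons summed to 504 ± 593 (SD, n = 8) against 463 ± 181 (SD, n = 4), with an exact permutation p of 0.958. That alcohol mean rested on WT high dose 1, at 1927 CPM, with the other alcohol libraries at 102 to 545 CPM. For Nrf2 target exons 1 high-dose library was at 228 CPM and the other alcohol libraries at 25.8 to 71.1 CPM. Leukocyte exons rose in 5 of 5 (median 0.62, adjusted p = 0.0431; adjusted p = 0.562 with an estimated correlation), and tRNA isoacceptors fell in 10 of 11 (median -1.17, adjusted p = 0.00543; adjusted p = 0.888 with an estimated correlation). Over all features 0 members of these lists passed, and adjusted over the list alone 1 tRNA isoacceptor and 0 of the Nrf2 target and leukocyte genes passed. The Nrf2 target call ended without WT high dose 2 (0.0640), the tRNA direction turned without WT control 1 (0.292), and the leukocyte call ended without any of WT control 1 and 3, WT low dose 1, 3 and 4 and WT high dose 1 (0.0556 to 0.303).

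In the Nrf2-/- set the comparison of ethanol with control asks how sperm RNA responds to alcohol without Nrf2. Exon reads of Nfe2l2 were listed at 20, 17, 0 and 5 counts in the controls and 4, 1, 9 and 10 in the ethanol libraries, against 4 to 47 in WT libraries, and 3 counts correspond to 0.765 CPM in the control at 0. The deleted part of the gene was not given in the sources used here, so these counts do not test the genotype. As lists, in the test with a preset correlation, let-7 miRNAs were higher with ethanol, and the germ cell miRNAs of the X-linked spermatogenesis cluster and of the miR-34 and miR-449 family were lower. In these lists 0 members passed, and they had adjusted p = 0.650, 0.650 and 0.172 with an estimated correlation. let-7c-5p was at 334720 CPM ± 145010 (SD, n = 4) against 164540 CPM ± 103490 (SD, n = 4), and miR-34c-3p at 34.1 CPM ± 12.5 (SD, n = 4) against 122 CPM ± 98.95 (SD, n = 4), with controls from 30.7 to 229 CPM. The controls also differed in sperm and spermatid exons, at 251, 296, 1029 and 1289 summed CPM, and the ethanol libraries lay between, at 306 to 417 CPM.

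The X-linked spermatogenesis cluster fell in 16 of 16 members, by a median of -0.69 (adjusted p = 0.000158; adjusted p = 0.650 with an estimated correlation), with miR-465a-5p at -1.01 (SE 0.46) and miR-743a-3p at -1.90 (SE 0.94). The let-7 family rose in 16 of 17 members, by a median of 0.90 (adjusted p = 0.000307; adjusted p = 0.650 with an estimated correlation), with let-7i-5p at 1.09 (SE 0.48) and let-7b-5p at 1.19 (SE 0.57). The miR-34 and miR-449 family, which acts in spermatogenesis and ciliated cells, fell in 5 of 6 members by a median of -1.59 (adjusted p = 0.00271; adjusted p = 0.172 with an estimated correlation). The miR-17-92 clusters fell in 8 of 11 members by a median of -0.50 (adjusted p = 0.0200; adjusted p = 0.699 with an estimated correlation), with miR-19b-3p at -1.59. In these 4 lists 0 members passed over all miRNAs and 0 adjusted over the list alone. The miR-34 and miR-449 call ended without miRNAs that have gaps (0.0572), and the miR-17-92 call without Nrf2-/- control 1 (0.0629), Nrf2-/- control 3 (0.0950) or Nrf2-/- ethanol 4 (0.461).

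edgeR called 0 of 237 miRNAs in Nrf2-/- sperm, with 3 at an unadjusted p under 0.05, fewer than the 11.85 that chance gives. DESeq2 called 0. Among the 10 with the lowest p, miR-296-5p had a log2 value of -1.74, miR-878-3p -1.43, miR-19a-3p -1.89, the liver miRNA miR-122-5p 2.38 and the lymphocyte miRNA miR-150-5p 1.79. The other tested miRNA lists had adjusted p values from 0.0816 (leukocyte) to 0.894 (miR-30 family). Median, mean and test differed in sign for the miR-10 group, miR-200 with miR-205, miR-30, miR-29 and Nrf2- or Keap1-targeting lists. miRNAs held 45.9% ± 7.78 (SD, n = 4) of the counts with ethanol and 32.9% ± 12.6 (SD, n = 4) in controls, with an exact permutation adjusted p of 0.457. Sense reads of transposable elements held 1.92% ± 0.224 (SD, n = 4) against 2.59% ± 0.370 (SD, n = 4), with an exact permutation p of 0.0286 and an adjusted p of 0.229.

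Smooth muscle and fibroblast exons rose with ethanol in 9 of 9 genes, by a median of 0.63 (adjusted p = 0.000447; adjusted p = 0.137 with an estimated correlation), among them Dcn, a matrix proteoglycan, at 15.2 CPM ± 1.70 (SD, n = 4) against 6.96 CPM ± 1.28 (SD, n = 4), and smooth muscle myosin Myh11 at 1.18. Hepatocyte exons rose in 7 of 7 genes, by a median of 0.85 (adjusted p = 0.00955; adjusted p = 0.985 with an estimated correlation), with albumin (Alb) at 113 CPM ± 68.4 (SD, n = 4) against 60.6 CPM ± 38.4 (SD, n = 4) and transthyretin (Ttr) at 1.33. In both lists 0 genes passed over all features and 0 adjusted over the list alone. Smooth muscle and fibroblast exons summed to 82.25 CPM ± 33.9 (SD, n = 4) against 59.8 CPM ± 18.7 (SD, n = 4), with an exact permutation p of 0.314 (adjusted p = 0.514). Hepatocyte exons summed to 135 CPM ± 112 (SD, n = 4) against 72.5 CPM ± 29.2 (SD, n = 4), with an exact permutation p of 0.343 (adjusted p = 0.514). The hepatocyte call ended without Nrf2-/- control 1 (0.174), Nrf2-/- ethanol 1 (0.0784) or Nrf2-/- ethanol 4 (0.261). edgeR called 0 of 9658 other features, with 452 at an unadjusted p under 0.05, fewer than the 482.9 that chance gives. It called 1 with no filter and 197 with the summed epididymis exons as a covariate.

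The Nrf2-/- controls split in their markers of other cells. Epididymis epithelium exons summed to 1683 and 1414 CPM in Nrf2-/- controls 1 and 2 and to 58.1 and 40.9 CPM in controls 3 and 4, while sperm and spermatid exons summed to 251 and 296 CPM in controls 1 and 2 and to 1029 and 1289 CPM in controls 3 and 4. Ethanol libraries lay between these values, from 193 to 461 CPM for the epididymis list. Sperm and spermatid exons were lower in 19 of 19 genes with ethanol (median -0.81, adjusted p = 0.280), Nrf2 target genes in 11 of 13 (0.971), epididymis genes in 5 of 7 (0.609), and red blood cell genes were higher in 4 of 4 (0.258). Ethanol metabolism, tRNA and all transposable element families had an adjusted p of 0.971. Median, mean and test differed in sign for the epididymis, ethanol metabolism, IAP sense, IAP antisense and RLTR sense lists.

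**Figure D3:**
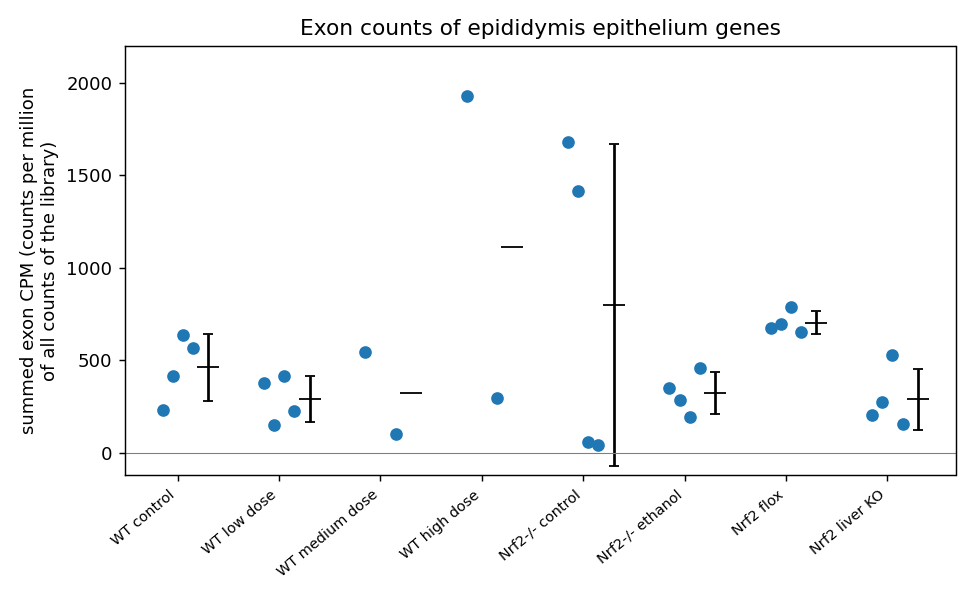
Each point is a library, grouped on the x axis, and the y axis is the summed exon CPM of epididymis epithelium genes (scaled to all counts), with the group mean as a tick and the SD as bars where a group has more than 2 libraries. Nrf2-/- controls range from 40.9 to 1683, and the 4 Nrf2 liver KO libraries (158 to 528) lie below the 4 Nrf2 flox libraries (651 to 791).

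The liver KO comparison asks whether loss of Nrf2 in the liver goes with a different sperm RNA content. Exons of epididymis marker genes were lower in Nrf2 liver KO libraries, at 291 summed CPM ± 165 (SD, n = 4) against 704 CPM ± 61.3 (SD, n = 4) in Nrf2 flox. The sum was 2.42-fold higher in flox and higher in every flox library than in any liver KO library (exact permutation p = 0.0286, adjusted p = 0.129). The list of these genes had adjusted p = 0.295 with an estimated correlation. Crisp1, a protein that coats sperm in the epididymis, was at 288 CPM ± 119 (SD, n = 4) against 525 CPM ± 29.6 (SD, n = 4). tRNA isoacceptors were higher as a list in the test with a preset correlation, but 0 passed over all features and the list had adjusted p = 0.345 with an estimated correlation. tRNA-Glu-GAG_ was at 134480 CPM ± 24667 (SD, n = 4) against 73183 CPM ± 22618 (SD, n = 4), with an adjusted p of 0.109. The epithelial miR-200a-3p was at 2698 CPM ± 1150 (SD, n = 4) against 5701 CPM ± 1157 (SD, n = 4). Nfe2l2 exons were listed at 0, 6, 22 and 4 counts in liver KO and 11, 9, 20 and 17 in flox sperm, a tissue the deletion does not target, and 3 counts correspond to 0.916 CPM in the library at 0.

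edgeR called 5 of 9836 other features, with 1211 at an unadjusted p under 0.05, where chance gives 491.8. Cd52 exons fell from 127 CPM ± 19.7 (SD, n = 4) to 42.7 CPM ± 23.2 (SD, n = 4), a log2 change of -1.56. HY1, a Y RNA that binds the Ro60 protein, had a log2 change of -1.30, the small nucleolar RNA gene Snord90 -2.03, and an intron of Slc28a3, a nucleoside transporter, -1.84, and all 4 had an adjusted p of 0.0295. Antisense reads of the conserved repeat UCON31 rose by 2.56 (adjusted p = 0.0406), at 10.4 CPM ± 5.90 (SD, n = 4) against 1.72 CPM ± 0.468 (SD, n = 4), and this feature was named after its values were seen. Each of the 5 separated all 4 liver KO from all 4 flox libraries. The count became 0 without Nrf2 flox 3, Nrf2 flox 4, Nrf2 liver KO 1 or Nrf2 liver KO 2, 1 without Nrf2 flox 2, 3 without Nrf2 liver KO 4 and 230 without Nrf2 liver KO 3. It became 74 with no filter and 0 with the summed epididymis exons as a covariate. That covariate includes Cd52 and separates liver KO (158 to 528 CPM) from flox (651 to 791 CPM) completely. Counts, list calls and directions of this comparison with the covariate therefore cannot tell it from the genotype.

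Epididymis epithelium exons fell in 7 of 7 genes, by a median of -1.22 (adjusted p = 3.18e-05; adjusted p = 0.295 with an estimated correlation), with Wfdc10 at -2.06 and Clu at -1.22, and 1 gene passed over all features and 6 adjusted over the list alone. Nrf2 target genes fell in 13 of 13, by a median of -0.75 (adjusted p = 0.000970; adjusted p = 0.295 with an estimated correlation), with the peroxiredoxin Prdx1 at -1.30, the ferritin heavy chain Fth1 at -0.64 and Gstm2 at -0.75. Ethanol metabolism genes fell in 4 of 4, by a median of -0.83 (adjusted p = 0.0322; adjusted p = 0.345 with an estimated correlation), with the retinaldehyde dehydrogenase Aldh1a1 at -1.23 and Adh5 at -1.25. Sperm and spermatid exons rose in 15 of 18, by a median of 0.36 (camera adjusted p = 0.00609, and 0.295 with an estimated correlation), with Spem1 at 0.73 and the outer dense fibre gene Odf1 at 0.61. Their summed exon CPM was 922 ± 35.6 (SD, n = 4) against 867 ± 80.4 (SD, n = 4), with an exact permutation p of 0.286 (adjusted p = 0.471). The exact permutation adjusted p was 0.129 for the summed Nrf2 target exons and 0.171 for ethanol metabolism. Over all features 0 members of these last 3 lists passed, and adjusted over the list alone 2 ethanol metabolism genes and 0 members of the other 2 lists passed. With the summed epididymis exons as a covariate the 3 calls ended, with adjusted p values of 0.625, 0.625 and 0.750, and the ethanol metabolism call also ended without Nrf2 flox 2 or 3 or Nrf2 liver KO 2 or 4 (0.0528 to 0.102).

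tRNA isoacceptors rose in liver KO sperm in 9 of 11, by a median of 0.65 (adjusted p = 0.000183; adjusted p = 0.345 with an estimated correlation), with tRNA-Leu-CTG at 0.94, tRNA-Glu-GAG_ at 0.88 and tRNA-Val-GTG at 0.89, while tRNA-Thr-ACY was lower at -1.38. Of these, 0 passed over all features and 8 adjusted over the list alone. Retroviral repeats rose as lists: RLTR sense in 59 of 77 names (median 0.24, adjusted p = 0.00370), IAP antisense in 11 of 12 (median 0.41, adjusted p = 0.0183), both with adjusted p = 0.345 with an estimated correlation, and RLTR antisense in 56 of 78 (median 0.15, adjusted p = 0.0463; adjusted p = 0.659 with an estimated correlation). Of the RLTR sense names 0 passed over all features and 1 adjusted over the list alone, and 0 passed either way in the other 2. RLTR4_Mm sense, the name with the lowest p, was lower, with a log2 value of -1.27 (adjusted p = 0.0813). With the epididymis covariate the tRNA call ended (0.289) and the directions of the 3 repeat lists turned, and without Nrf2 liver KO 4 the IAP antisense (0.140) and RLTR antisense (0.586) calls ended, the latter also without Nrf2 flox 1 (0.0829) or 3 (0.165). Smooth muscle and fibroblast genes were lower in 9 of 9 (adjusted p = 0.0749), and spermatocyte (0.682), hepatocyte (0.782), IAP sense (0.575), L1Md (0.329 sense, 0.118 antisense), B1 (0.131 sense, 0.527 antisense) and B2 (0.329 sense, 0.520 antisense) lists did not pass.

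Of the miRNA lists, the miR-200 family with miR-205 fell in liver KO sperm in 9 of 10 members, by a median of -0.64 (adjusted p = 0.00454; adjusted p = 0.513 with an estimated correlation), with miR-141-3p at -1.35 and miR-200b-3p at -0.96; 0 passed over all miRNAs and 3 adjusted over the list alone. The Nrf2- or Keap1-targeting miRNAs, a list that shares miR-200a and miR-141 with the epithelial list, fell in 11 of 14, by a median of -0.60 (adjusted p = 0.0164; adjusted p = 0.513 with an estimated correlation). The let-7 family rose in 10 of 10 members, by a median of 0.37 (adjusted p = 0.0490; adjusted p = 0.526 with an estimated correlation), with let-7a-5p at 0.78 and let-7d-5p at 0.86. In the last 2 lists 0 members passed over all miRNAs and 0 adjusted over the list alone. The 3 calls ended with the epididymis covariate (0.787, 0.467 and 0.0831), the first also without Nrf2 liver KO 4 (0.0950), the second without Nrf2 liver KO 2 (0.0533), and the let-7 call without Nrf2 flox 1 (0.0545), Nrf2 flox 2 (0.0536), Nrf2 liver KO 1 (0.0791) or Nrf2 liver KO 2 (0.120). With the total of all classes as the library size, the median over all miRNAs moved from 0.0309 to -0.295, so the let-7 values are relative to that median.

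edgeR called 0 of 295 miRNAs in liver KO sperm, and DESeq2 called 0. In edgeR 41 had an unadjusted p under 0.05 where chance gives 14.75 (18 higher and 23 lower, smallest adjusted p 0.311). The 10 with the lowest p held miR-151-5p (log2 -1.21), miR-200a-3p (-1.08), the hypoxia-responsive miR-210-3p (-1.39), miR-101a-3p (-1.31), miR-148a-3p (-1.73), miR-190a-5p (-1.35), miR-152-3p (-1.03), miR-532-3p (1.34), the gonad miRNA miR-202-3p (1.38) and miR-224-5p (1.39). The 4 liver miRNAs were lower in 4 of 4 (adjusted p = 0.130), with 0 past the threshold over all miRNAs and 1 adjusted over the list alone. Other tested lists had adjusted p values from 0.0603 (miR-29 and miR-30 families) to 0.981, and median, mean and test differed in sign for the X-linked spermatogenesis, red blood cell and brain lists. Structural RNA held 39.3% ± 5.55 (SD, n = 4) of liver KO counts and 32.7% ± 4.27 (SD, n = 4) of flox counts (exact permutation p = 0.114, adjusted p = 0.305), exons held 8.11% ± 1.18 (SD, n = 4) and 10.2% ± 0.409 (SD, n = 4) (exact permutation p = 0.0286, adjusted p = 0.229), and miRNAs held 16.3% ± 3.58 (SD, n = 4) and 17.99% ± 3.58 (SD, n = 4).

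The difference between the alcohol response of WT sperm (all doses) and that of Nrf2-/- sperm was tested for each miRNA. edgeR called 0 of 372 miRNAs, with 19 at an unadjusted p under 0.05 where chance gives 18.6. The smallest adjusted p was 0.120, for miR-22-5p. The list calls of the WT and Nrf2-/- sets were not tested against each other.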

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

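The tests of the gaps, the epididymis markers and the red blood cell RNA were chosen after those results were seen. Each value was tested within each group of 4 libraries. In 108 such tests, a library stood apart by Dixon's 95% criterion 9 times, where chance gives about 1 in 20 tests, or 5.40, and the 9 fell in 3 groups.

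WT control 1 stood apart from the other WT controls in 4 values. Its structural RNA share was 75.8% (95% Wilson interval 75.7% to 75.8%) against 22.5% to 28.7%. Its shares of transposable elements were 1.80% in sense, against 4.96% to 5.14%, and 2.12% in antisense, against 6.28% to 6.65%. Its sperm and spermatid exons summed to 342 CPM against 681 to 736 CPM. Nrf2-/- ethanol 4 had 6.43% introns against 4.62% to 4.84%, and 0.0956% miRNA hairpins against 0.147% to 0.151%. Nrf2 flox 3 had 748 CPM of sperm and spermatid exons against 894 to 923 CPM, 183 CPM of Nrf2 target exons against 136 to 143 CPM, and 74.2 CPM of ethanol metabolism exons against 46.0 to 49.8 CPM. Within a library the class shares sum to the whole, and the summed exon CPM are scaled to all counts, including structural RNA. The values of WT control 1 are therefore not independent of each other, and its low exon CPM depends on that scaling.

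Abundant miRNAs such as miR-16-5p and let-7c-5p were listed at 0 in single libraries of the WT and Nrf2-/- tables. Too few reads could not be tested over the entries, since a gap was defined by at least 50 expected reads. Of the entries so selected, 48.1% had over 1000 reads expected, and miR-16-5p in WT control 4 had 345357. The tables argue against counting under the precursor, since in 2 of 199 entries the precursor gained at least 50 percent of the expected reads. The tables argue against alcohol exposure as well, since 35.1% of the entries lay in control libraries without alcohol, with 5 to 17 in each WT control and 5 to 10 in each Nrf2-/- control. WT alcohol libraries held 12.3 ± 2.92 gaps (SD, n = 8) and WT controls 11.5 ± 5.196 (SD, n = 4; exact permutation p = 0.828). How the counts were made was not given and could not be tested.

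Epididymis epithelium exons such as Cd52 and Crisp1 differed widely within groups, from 40.9 to 1683 summed CPM in Nrf2-/- controls. Over 28 libraries as deviations from group means, library depth was not related to them (r = -0.0699, permutation p = 0.69), which argues against depth. RNA of epididymal epithelium may be a source and stays open: the relation with miR-200 and miR-205 had r = 0.623 (permutation p = 0.085, adjusted 0.15 over 9 relations; rho = 0.537, p = 0.061) and r = 0.549 without the 2 farthest libraries. Fewer sperm among the cells stays open too. The relation with sperm and spermatid exons had r = -0.711 (permutation p = 0.17, adjusted 0.26). Relations with exons of other cells differed in sign. Leukocyte exons had r = 0.714 (permutation p = 0.00014, adjusted 0.00063) and smooth muscle and fibroblast exons r = 0.514 (permutation p = 0.00046, adjusted 0.0014). Red blood cell exons had r = -0.318 (permutation p = 0.23, adjusted 0.3) and rho = -0.21 (permutation p = 0.42). In the liver KO comparison the marker values separate the groups completely, so the covariate and the genotype cannot be told apart there.

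Red blood cell RNA, such as Hbb-bs and miR-451a, had higher mean values at low dose. In edgeR 0 members of these lists passed over all miRNAs or all other features. Library depth was not related to red blood cell exons over the 28 libraries (r = -0.0448, permutation p = 0.87), which argues against depth. Residual red blood cells may be the source of this RNA. Their exons and miRNAs had r = 0.554 (permutation p = 0.033, adjusted 0.074 over 9 relations) and rho = 0.539 (permutation p = 0.033). Without the 2 farthest libraries r was 0.438, and 2 miRNAs were used in the WT table. Whether alcohol exposure lies behind the difference stays open, with an exact permutation adjusted p of 0.257, the lowest that 1 list alone can reach with 4 against 4 libraries.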

How the results depend on the processing

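The tests without miRNAs that have gaps, with the epididymis covariate and without WT controls 1 and 3 together were chosen after the data were seen. The list tests with each library left out were not planned either and are counted with the added values. Among the counts and list counts, 210 of the planned values stayed on the same side and within 1.5 times, 18 moved by more than that, 29 rose from 0 and 23 fell to 0. For the added values these numbers were 70, 23, 5 and 8. Where a value below differs, the cause was not tested.

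With DESeq2's Wald test the count of miRNAs moved from 0 to 24 at low, 7 at medium and 7 at high dose, 13 for the pooled doses and 20 for any alcohol. Without miRNAs that have gaps DESeq2 gave 22, 0, 0, 1 and 17. With no filter, edgeR gave 2 miRNAs at low dose and 1 for any alcohol, and with only the groups compared it gave 2 at low dose. For other features, no filter gave 102 at low dose, 9 at medium dose, 4 pooled, 14 for any alcohol, 1 in Nrf2-/- and 74 in liver KO.

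The labels do not say whether the replicate numbers pair the libraries. Correlations of same-numbered libraries were 0.221, 0.145, 0.2 and 0.0944 in Nrf2-/- and differed in sign in liver KO (-0.246, 0.0965, -0.297 and 0.418). In Nrf2-/-, controls 1 and 2 correlated positively with ethanol 1 and 2 (0.145 to 0.344), as did controls 3 and 4 with ethanol 3 and 4 (0.0944 to 0.329). Pairs across these numbers were negative (-0.297 to -0.0509). The main Nrf2-/- test did not model this structure, and its source was not tested. With a replicate block, other features numbered 53 at low dose, 1 pooled, 2 for any alcohol and 30 in liver KO, and 1 miRNA was called in liver KO. With the epididymis covariate they numbered 139 at low dose, 1 pooled, 4 for any alcohol, 197 in Nrf2-/- and 0 in liver KO. Without WT controls 1 and 3 together, 2 were called at low dose and 0 for any alcohol.

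With an estimated correlation, 0 miRNA lists passed in any comparison. By fry, 1 passed at low dose, 1 in Nrf2-/- and 0 elsewhere. Without miRNAs that have gaps, 1 passed at medium, 0 at high dose and 0 pooled, and with the covariate 1 passed at medium dose.

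Leaving out each library in turn, miRNA counts ranged from 0 to 2 at medium dose, 0 to 5 at high dose, pooled and for any alcohol, and 0 to 1 for the interaction, and stayed 0 elsewhere. The highest counts came without WT high dose 1 (5 at high dose, pooled and for any alcohol) and WT medium dose 1 (2 at medium dose). Other features ranged from 0 to 21 at low dose, 0 to 2 at medium dose, 0 to 5 pooled, 0 to 5 for any alcohol and 0 to 230 in liver KO, the last without Nrf2 liver KO 3. miRNA lists ranged from 2 to 5 at low dose, 0 to 3 at medium dose, 0 to 2 at high dose, 0 to 3 pooled, 1 to 4 for any alcohol, 3 to 5 in Nrf2-/- and 1 to 4 in liver KO. Classes past the threshold ranged from 0 to 4 for any alcohol, the latter without WT control 1.

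Directions reversed in these cases. Without WT high dose 2, miR-451a at high dose became -0.77 and the pooled Nrf2 target list turned (adjusted p = 0.814). Without WT control 1, the tRNA list turned at low dose (0.195), high dose (0.857), pooled (0.355) and any alcohol (0.292), and at low dose the share difference became -3.79 percentage points for piRNA clusters and 3.96 for structural RNA. Without WT medium dose 2, RLTR sense (0.690) and antisense (0.756) turned at medium dose. With the covariate in liver KO, IAP antisense (0.625), RLTR sense (0.625) and RLTR antisense (0.404) turned. Without the most abundant class in the denominator, the difference became -1.22 percentage points for piRNA clusters at low dose, 4.31 for structural RNA in Nrf2-/-, 1.77 for piRNA clusters in liver KO and 0.172 for miRNAs in liver KO. Without Nrf2 flox 2, piRNA clusters in liver KO became 0.284.

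Over the libraries left out, miR-451a at high dose ranged from -0.77 to 3.27 and the adjusted p of the tRNA list from 0.00225 to 0.195 at low dose, 0.000153 to 0.857 at high dose, 0.000261 to 0.355 pooled and 0.000197 to 0.292 for any alcohol. It ranged from 2.87e-05 to 0.690 for RLTR sense and 0.000715 to 0.756 for RLTR antisense at medium dose, and from 1.17e-06 to 0.814 for the pooled Nrf2 targets. Share differences ranged from -3.79 to 5.52 percentage points for piRNA clusters and -13.8 to 3.96 for structural RNA at low dose, and from -2.54 to 0.284 for piRNA clusters in liver KO.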

Other observations

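The relations between marker lists were chosen after the markers were seen, while the other splits of the libraries were planned, except for the count of other features at an unadjusted p under 0.05 at low dose, with any alcohol and in liver KO, which was chosen after the splits were seen. The number of splits drawn for any alcohol was raised after a smaller draw had been seen.

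Over 28 libraries as deviations from group means, Nrf2 target exons followed epididymis epithelium exons with r = 0.973 (permutation p = 1e-05, the smallest the permutations can give, adjusted 9e-05 over 9 relations), rho = 0.969 (p = 1e-05) and r = 0.962 without the 2 farthest libraries, Nrf2-/- controls 1 and 4. The gene lists of the epididymis and of Nrf2 targets share 0 genes. Leukocyte exons followed the epididymis markers with r = 0.714 (permutation p = 0.00014, adjusted 0.00063), rho = 0.73 (p = 0.00073) and r = 0.649 without those libraries. Smooth muscle and fibroblast exons had r = 0.514 (permutation p = 0.00046, adjusted 0.0014), rho = 0.616 (p = 0.00082) and r = 0.500 without them. Sperm and spermatid exons had r = -0.711 (permutation p = 0.17, adjusted 0.26), rho = -0.437 (p = 0.11) and r = -0.492 without them.

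Other splits of the low-dose and control libraries were fitted in the same way. In 1 of 35 splits, the real one, as many miRNAs had an unadjusted p under 0.05 (45, highest other 21). As many other features passed in 1 of 35 splits (10, highest other 0). This is the smallest share that 35 splits can give, and the split counts were not adjusted for their number. A random split is therefore not excluded for these counts. In 2 of 35 splits as many other features had an unadjusted p under 0.05 (1244, highest other 1454, with WT controls 1 and 2 and WT low dose 2 and 4 on the control side). As many miRNA lists passed in 2 of 35 splits (4, highest other 4), so a random split is not excluded for the lists. For any alcohol, 100 of the 495 possible splits were drawn and the others were not fitted. Of these, 3 of 100 gave as many miRNAs (40, highest other 58, with WT controls 1 and 4, WT high dose 1 and WT medium dose 1 on the control side). The share was not adjusted over the counts examined, and the draw was enlarged after a smaller one had been seen. A random split is therefore not excluded for that count. In 10 of 100 as many lists passed (4, highest other 5) and in 12 of 100 as many other features (1, highest other 797). At an unadjusted p under 0.05, 48 of 100 gave as many other features (725, highest other 3718). A random split is not excluded for these either, and what the split with the highest count separates was not tested.

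For the pooled doses, 12 of 35 splits gave as many miRNAs (21, highest other 51), 22 of 35 as many lists (1, highest other 6) and 30 of 35 as many other features at an unadjusted p under 0.05 (501, highest other 3083), so a random split is not excluded. For Nrf2-/-, 16 of 35 splits gave as many miRNAs (3, highest other 58) and 8 of 35 as many lists (4, highest other 8). At an unadjusted p under 0.05, 13 of 35 gave as many other features (452, highest other 4302, with Nrf2-/- controls 1 and 2 and Nrf2-/- ethanol 1 and 4 on the control side). A random split is not excluded, and what the split with 4302 features separates was not tested. For liver KO, 5 of 35 splits gave as many miRNAs (41, highest other 54), 13 of 35 as many lists (3, highest other 5) and 2 of 35 as many other features (5, highest other 192, with Nrf2 flox 2 and Nrf2 liver KO 3 exchanged) or as many at an unadjusted p under 0.05 (1211, highest other 1825, the same split), so a random split is not excluded there either.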
